A study of Homo sapiens with 18 samples.

How the data were processed

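Open chromatin was profiled by Fast-ATAC, in which a transposase cuts accessible DNA in permeabilised nuclei, in 15 human cell types and 3 melanoma cell lines, 18 samples in all. Per the labels, biological replicates were assayed, and the series text gives 2 per profile. The authors deposited 1 list of peak positions per sample, so each cell type or line counted as 1 sample and no spread between replicates of a cell type could be computed. The deposited lists give a chromosome, a start and an end on each line and no height, score or p-value. The submitters' processing notes name the build hg19 and the tools Bowtie2, STAR, Picard and MACS2, without versions or settings; how the 2 replicates entered a list is not given in the sources used here. Read depth is unknown, so the length of a list, which also depends on depth and on the caller's threshold, was the nearest measure of it that could be given. Intervals and p-values given here cover counting error or the choice of samples only.

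In 17 of the lists an interval stood on 1 to several identical lines; these were counted once, and the meaning of the repeats is not given in the sources used here. The airway list held each interval once and had the narrowest intervals. Chromosomes 1 to 22 and X were used. All lists were merged into consensus regions where intervals overlapped by 1 bp or more, and a region was called open in a sample when at least 1 of its intervals fell in it. Coordinates are on hg19 and counted from 1. Similarity was the Jaccard index, the number of regions open in both samples divided by the number open in either. A region was called rare when it was open in at most 9 samples. Shares carry 95% Wilson intervals.

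Group differences were tested with exact one-sided permutation tests over every choice of as many samples, with Benjamini-Hochberg adjustment over 9 tests. These designs, the alternatives and the rule naming the 3 widest regions of the melanoma-only, absent from melanoma, pigment cell and epithelial sets were fixed before the data were examined. The test of rare melanocyte regions, that of covered length and the analysis of 100 kb windows were added after the data were seen, as were the alternatives that leave out the library labelled astrocytes, the airway list or the 4 shortest lists, or keep the widest intervals of each list. No annotation or sequence of hg19 was used, so the planned results on promoters, genes, gene lists and sequence motifs were not run, and no gene is named.

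In place of genes, open regions were counted by their midpoint in windows of 100 kb, and windows with a mean of at least 1 open region were tested with limma (trend) on log2(open regions + 1), with log2 of the sample's total as a covariate and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on that scale and understate changes of windows with few regions. Named windows followed the rule planned for genes, up to 12 in each direction with the largest difference among those past the threshold, where the median of the smaller group lay outside the interquartile range of the other. The text prints some of these. The window described by how many regions of a set it held, and the widest region of the set shared by airway, bladder, mammary, uterine and keratinocyte cells, were chosen after their values were seen.

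The region calls were tested on simulated lists, where all 207 melanoma-only regions among 19961 simulated regions were found. The simulated regions lay too far apart to merge with each other, so this checks the counting only. Merging of close regions was not tested. The window test was run on 17132 simulated windows of the melanoma comparison. It recovered 89% of 100 windows raised 4-fold in the lines and 4% of 100 raised 2-fold, with 3 unchanged windows called. The raised windows had a mean of at least 2 open regions beforehand. Decreases, and changes in windows with fewer open regions, were not simulated. Apart from the increases the simulated counts varied only by list length and counting error. The 3 calls therefore do not measure the error rate where cell types vary more. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.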

Results

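Peak lists from 18 human samples were compared. The samples were epithelial cells of 11 organs, a keratinocyte culture treated with 1.2 mM calcium for 6 days to induce differentiation, melanocytes, a culture labelled astrocytes, the B-lymphoblastoid line GM12878, and the melanoma lines COLO 829, SK-MEL-5 and WM-266-4. Per the labels, the melanoma lines were kept with DMSO, a solvent, for 24 hours, in an amount that differs between the lines and could not be checked. The labels name DMSO for no other sample, so it goes with every melanoma comparison. The lists held between 16321 and 90817 distinct intervals. The library labelled astrocytes had the shortest list, followed by the ovarian, melanocyte and prostate lists with 21579, 24366 and 36527 intervals; the other 14 held at least 57536. Together they formed 229900 consensus regions that covered 147.7 Mb.

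Most consensus regions were open in few of the samples. Of all regions, 80448 (35.0%) were open in a single sample, and 10223 (4.45%) were open in all 18, against 2.5e-06 expected if the samples were independent. Without the 4 shortest lists 16446 were open in all remaining samples. Single lists differed: the colon list had 21710 regions open in 2 to 9 samples and 30817 open in 10 to 17, and the SK-MEL-5 list had 36521 and 20382. Regions open everywhere made up 63.5% of the short list labelled astrocytes and 12.7% of the long bladder list. Peaks were wider there: in each of the 15 samples with 100 or more regions of their own, the median interval in regions open everywhere, 580 to 1059 bp, was wider than that sample's median in its own regions, 214 to 641.5 bp. There is 1 list per cell type, so these values have no replicate error.

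GM12878, a blood-derived line, had the most regions of its own. It had 20163 regions open in no other sample, 37.2% of its list (95% Wilson interval 36.8 to 37.6%), and its Jaccard index with the other 17 samples was at most 0.283. SK-MEL-5 followed with 15865 such regions (19.1%), WM-266-4 with 8910 (11.9%) and COLO 829 with 6406 (8.10%). Among the primary cells the highest share was that of the keratinocytes, 6146 regions (7.96%), and the uterine list came next with 5425 (6.35%). The prostate, ovarian and astrocyte-labelled lists had 5, 2 and 0 regions of their own. GM12878-only regions were densest in the window of chromosome 6 from 300001 to 400000, where they made up 22 of 29 regions.

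**Figure D1:**
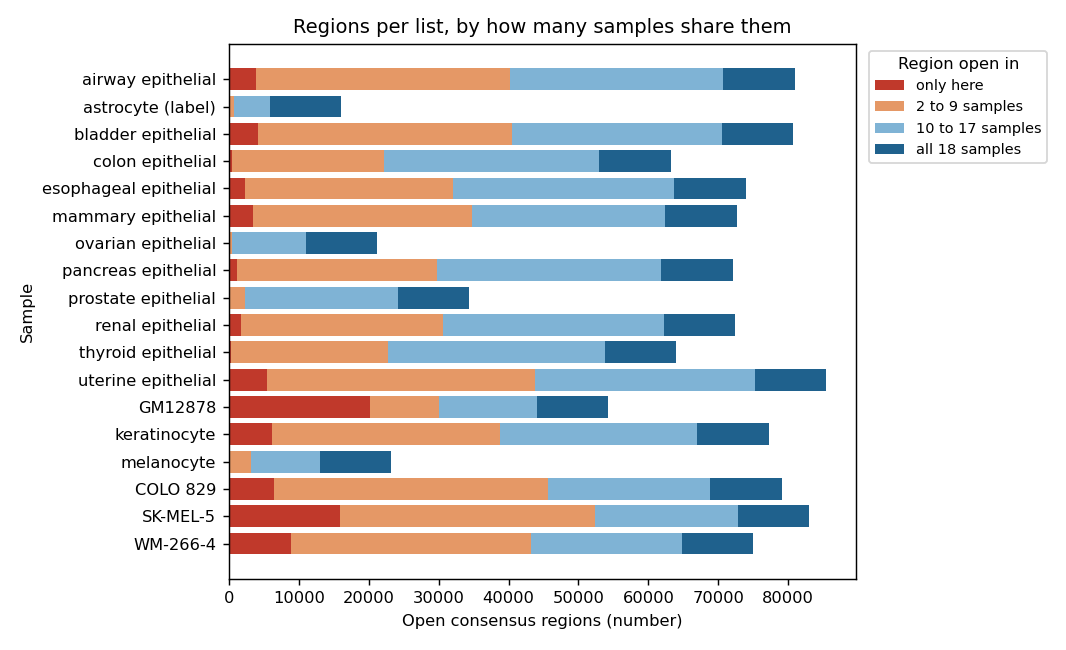
Open consensus regions in each sample (horizontal axis, number of regions), with each bar split by the number of samples in which a region was open. GM12878 and SK-MEL-5 have the largest parts open in no other sample (20163 and 15865 regions), and the 4 shortest lists consist mostly of regions open in 10 or more samples.

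The comparison of the melanoma lines with all other cell types asked which regions were called open in the lines alone. The only normal pigment cell list, that of the melanocytes, was short, with 23207 regions against 75023 to 82991 in the lines. A region closed in it may be missing for that reason, so the count does not separate malignant from normal pigment cells. Without the 4 shortest lists, melanocytes among them, it was 10723. The 3 lines shared 10473 regions that were closed in all 15 other samples, the most frequent combination of more than 1 sample in the data. The next highest number for any other choice of 3 samples was 1033, for airway, mammary and keratinocyte cells. The widest melanoma-only regions lay on chromosome 22 from 38380227 to 38382867, on chromosome 12 from 122525637 to 122527983 and on chromosome 3 from 37645310 to 37647613. No other choice of 3 of the 18 samples gave as many (exact one-sided permutation p = 0.00123, the smallest possible here; adjusted 0.00265). With every list cut at random to the length of the shortest, 116 were left against at most 108 for another choice, and with the widest intervals of each list kept to that length, 1190 against 215. In 500 bp bins the number was 16597, and with the wider 50% of each list 5480.

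Relative to list length, whole windows held more or fewer open regions in the melanoma lines than in the other samples. Of 17294 windows of 100 kb tested with limma, 1819 were higher in melanoma and 2207 lower, at a Benjamini-Hochberg adjusted p under 0.05. Higher and lower are meant after adjustment for each sample's total of open regions, and the means printed below are not adjusted. On chromosome 13 from 78400001 to 78500000 the lines had 11.7 ± 3.51 open regions (SD, n = 3) and the other samples 0.467 ± 0.743 (SD, n = 15), a log2 difference of 3.19 with an SE of 0.40. On chromosome 3 from 15700001 to 15800000 the means were 8 ± 1 and 0.0667 ± 0.258. On the same chromosome from 70000001 to 70100000 they were 7.67 ± 0.577 and 0.200 ± 0.414. In the opposite direction, the window of chromosome 8 from 10500001 to 10600000 had no open region in any of the 3 lines and 9.27 ± 6.20 in the others (log2 difference -3.81, SE 0.52). It was also empty in 3 of the 4 samples that are neither melanoma nor epithelial. On chromosome 16 from 81500001 to 81600000 the lines had 0.333 ± 0.577 and the others 7.80 ± 4.78, with 1 of those 4 samples empty. The number of windows past the threshold was 1277 without the covariate and 2202, 2508 and 2494 with COLO 829, SK-MEL-5 or WM-266-4 left out. More windows were higher than lower in 250 kb windows (1279 and 1042) and without the filter on low windows (4850 and 2416), and with lists cut at random to the shortest 0 were higher and 78 lower.

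Regions open in every other cell type and closed in all melanoma lines were few. There were 25, and the widest lay on chromosome 5 from 121412411 to 121414440, on chromosome 11 from 117856581 to 117858315 and on chromosome 1 from 36771497 to 36773013. For 19 choices of 3 samples, the lines included, the number was as large (exact one-sided permutation p = 0.0233, adjusted 0.0262), the highest being 1248 for the 3 shortest lists, those of the astrocyte-labelled, ovarian and melanocyte samples. Without the 4 shortest lists, when fewer lists had to be open, the count was 741. With the widest intervals of each list kept to the length of the shortest it was 195, against at most 26 for any other choice (exact permutation p = 0.00123). That setting also shortens the lists of the lines, and why the count rose was not tested. With COLO 829, SK-MEL-5 or WM-266-4 left out the counts were 34, 65 and 73, with exact permutation p of 0.103, 0.0588 and 0.0588.

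The melanoma lines resembled each other more than other samples. Their Jaccard indices were 0.572 for COLO 829 with WM-266-4, 0.518 for COLO 829 with SK-MEL-5 and 0.443 for SK-MEL-5 with WM-266-4, and 0.280 ± 0.0516 (SD, 45 pairs) between them and the other 15 samples. The mean within the lines exceeded that with the others by 0.231, which 12 choices of 3 samples reached, the lines included (exact one-sided permutation p = 0.0147, adjusted 0.0189). Their peaks covered 56.5 ± 0.974 Mb (SD, n = 3) against 35.3 ± 11.3 Mb in the other samples (SD, n = 15; exact one-sided permutation p = 0.00123, adjusted 0.00265). Without COLO 829 the difference in similarity was 0.170 (exact permutation p = 0.169), with the overlap coefficient, which divides by the shorter list, 0.120 (exact permutation p = 0.116), with the widest intervals of each list kept to the length of the shortest 0.146 (exact permutation p = 0.0147), and with lists cut at random to that length 0.0111 (exact permutation p = 0.143).

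Melanocytes, the normal cells of the lineage, shared a small specific set of regions with the lines. In total 250 regions were open in melanocytes and all 3 lines and closed in the 14 other samples, against at most 21 for the melanocytes with any other 3 samples. The widest were on chromosome 14 from 48143416 to 48145730, on chromosome 5 from 159903142 to 159905360 and on chromosome 10 from 660716 to 662703. No other of the 680 choices gave as many (exact one-sided permutation p = 0.00147, the smallest possible; adjusted 0.00265). The number was 821 in 500 bp bins, 533 with 50% of a region covered, 141 with the wider 50% of each list and 138 with the widest intervals kept to the length of the shortest, each above any other choice (exact permutation p = 0.00147), and 4 with lists cut at random to that length (exact permutation p = 0.238). Of the 790 melanocyte regions closed in all 14 other samples, WM-266-4 had 63.04% open (95% Wilson interval 59.6 to 66.3%), COLO 829 had 52.4% (48.9 to 55.9%) and SK-MEL-5 had 43.7% (40.3 to 47.2%).

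Over the whole melanocyte list the similarity to the lines was lower by the Jaccard index and the phi coefficient, and higher only by the overlap coefficient. All 3 lines had 80.1% of the 23207 melanocyte regions open, and 3.55% (823 regions) were closed in all of them. WM-266-4 alone had 91.4% open, COLO 829 had 89.5% and SK-MEL-5 had 86.5%, and the uterine and airway samples had 90.6% and 89.8%. The mean Jaccard index of the melanocytes was 0.254 with the lines and 0.309 with the other samples, a difference of -0.05 (exact one-sided permutation p = 0.874), and -0.07 with the widest intervals of each list kept to the length of the shortest (exact permutation p = 0.999). The phi coefficient, a correlation of the open and closed calls, gave a difference of -0.0522 (exact permutation p = 0.794). The Jaccard index was highest with other short lists, 0.525 with ovarian and 0.475 with the astrocyte-labelled sample, and the overlap coefficient over the same lists gave 0.0585 in the other direction (exact permutation p = 0.0397).

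Among the 3205 rare melanocyte regions the lines came first. WM-266-4 had 67.6% of them open, COLO 829 had 60.4% and SK-MEL-5 had 49.8%, and the next was the uterine sample with 39.4%. The mean was 59.3 ± 8.96% in the lines (SD, n = 3) and 18.8 ± 14.2% in the other 14 samples, a difference of 40.5 percentage points that no other of the 680 choices reached (exact one-sided permutation p = 0.00147, adjusted 0.00265). It was 3.45 points with the widest intervals of each list kept to the length of the shortest (exact permutation p = 0.253), and -6.93 points with lists cut at random. A melanocyte region open in 9 or more other samples is not rare. This rule therefore holds down the shares of a large related group, such as the 11 epithelial samples, more than those of the 3 lines.

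**Figure D2:**
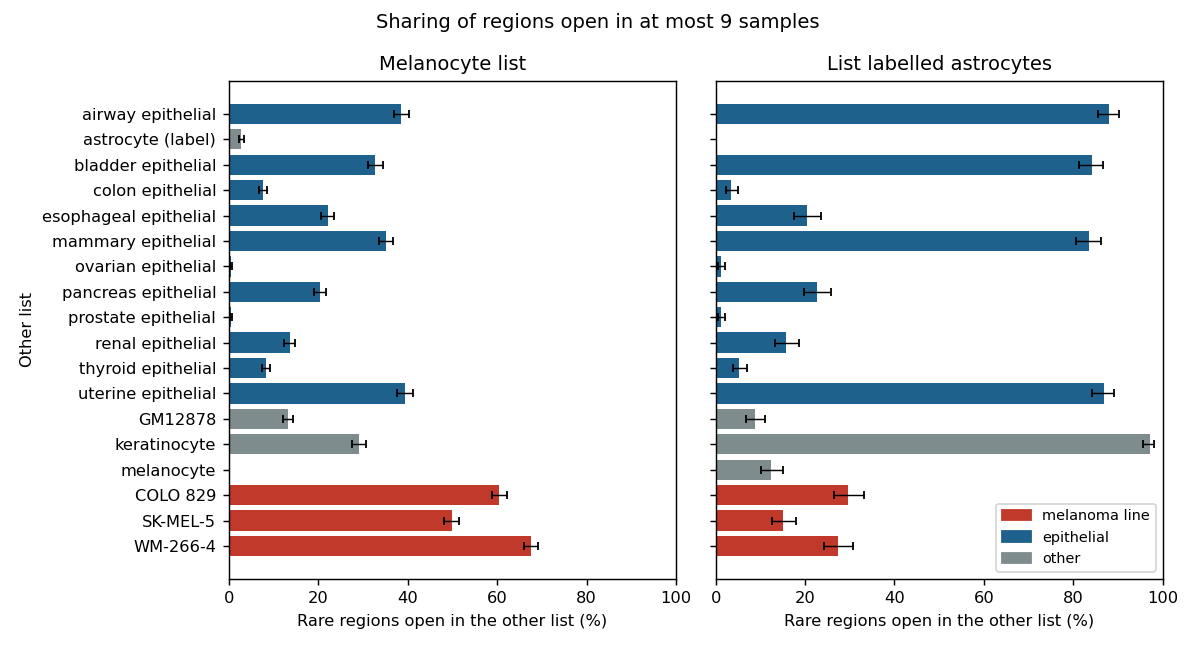
Share of the rare regions (open in at most 9 samples) of the melanocyte list, left, and of the list labelled astrocytes, right, that were open in each other list, in percent, with 95% Wilson intervals as error bars. Melanoma lines lead for melanocytes (49.8 to 67.6%), and keratinocytes lead for the list labelled astrocytes (97.0%).

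The 11 epithelial samples shared more regions with one another than with the other 7 samples. Their mean Jaccard index was 0.492 ± 0.142 (SD, 55 pairs) within the group and 0.312 ± 0.0978 (SD, 77 pairs) with the others, a difference of 0.180 that 12 choices of 11 samples reached, the real one included (exact one-sided permutation p = 0.000377, adjusted 0.00265). With lists cut at random to the shortest it was 0.00895 (exact permutation p = 0.285). The keratinocytes, which the labels place outside the group, reached 0.569 ± 0.0313 (SD, 4 pairs) with airway, bladder, mammary and uterine cells. These 5 samples alone shared 4431 regions, the widest on chromosome 10 from 20104717 to 20106900. Open in all 11 epithelial samples and closed in the other 7 were 77 regions, with the widest on chromosome 7 from 3283044 to 3284668, on chromosome 20 from 49031480 to 49032970 and on chromosome 5 from 153577306 to 153578779. With the keratinocytes also open there were 293. Both counts need a region to be in the short ovarian and prostate lists, so they are limited by these. Open in keratinocytes and every epithelial list but the ovarian one, and closed elsewhere, were 2131 regions. With the prostate list closed as well there were 584.

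By window, and relative to list length, 1291 were higher in epithelial samples and 651 lower (limma, adjusted p under 0.05). The other 7 samples include the melanoma lines, so this comparison overlaps with the melanoma one. The window of chromosome 8 from 10500001 to 10600000, empty in melanoma, had 11.2 ± 4.42 open regions in epithelial cells (SD, n = 11) and 2.29 ± 6.05 in the others (SD, n = 7). On chromosome 2 from 121900001 to 122000000 the means were 7 ± 2.24 and 1 ± 1.83. The window of chromosome 13 that was highest in melanoma had 0.273 ± 0.647 in epithelial cells and 5.57 ± 6.08 in the others. Without the 6 shared-medium samples 1 window passed. Without the covariate 734 windows were higher and 133 lower, without the filter 1417 and 1958, and with lists cut at random to the shortest 3 and 0.

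Of the epithelial samples, 6 (colon, esophageal, ovarian, pancreas, renal and thyroid) were grown in a single supplier medium. Colon and thyroid cells had the highest Jaccard index of all pairs, 0.832, followed by esophageal and pancreas cells with 0.779, renal and thyroid cells with 0.775 and colon and renal cells with 0.760. Colon, esophageal, pancreas, renal and thyroid cells alone shared 1370 regions. Within the 6 the mean index was 0.581 ± 0.208 (SD, 15 pairs) and between them and the other 5 epithelial samples 0.440 ± 0.0802 (SD, 30 pairs), a difference of 0.141 that 6 choices of 6 samples reached, the real one included (exact one-sided permutation p = 0.0130, adjusted 0.0189). Without the 4 shortest lists, which include the ovarian and prostate lists, it was 0.255 (exact permutation p = 0.00794, the smallest possible there), and with lists cut at random to the shortest 0.0222 (exact permutation p = 0.0952). Medium and organ cannot be separated here, because each organ was grown in 1 medium.

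**Figure D3:**
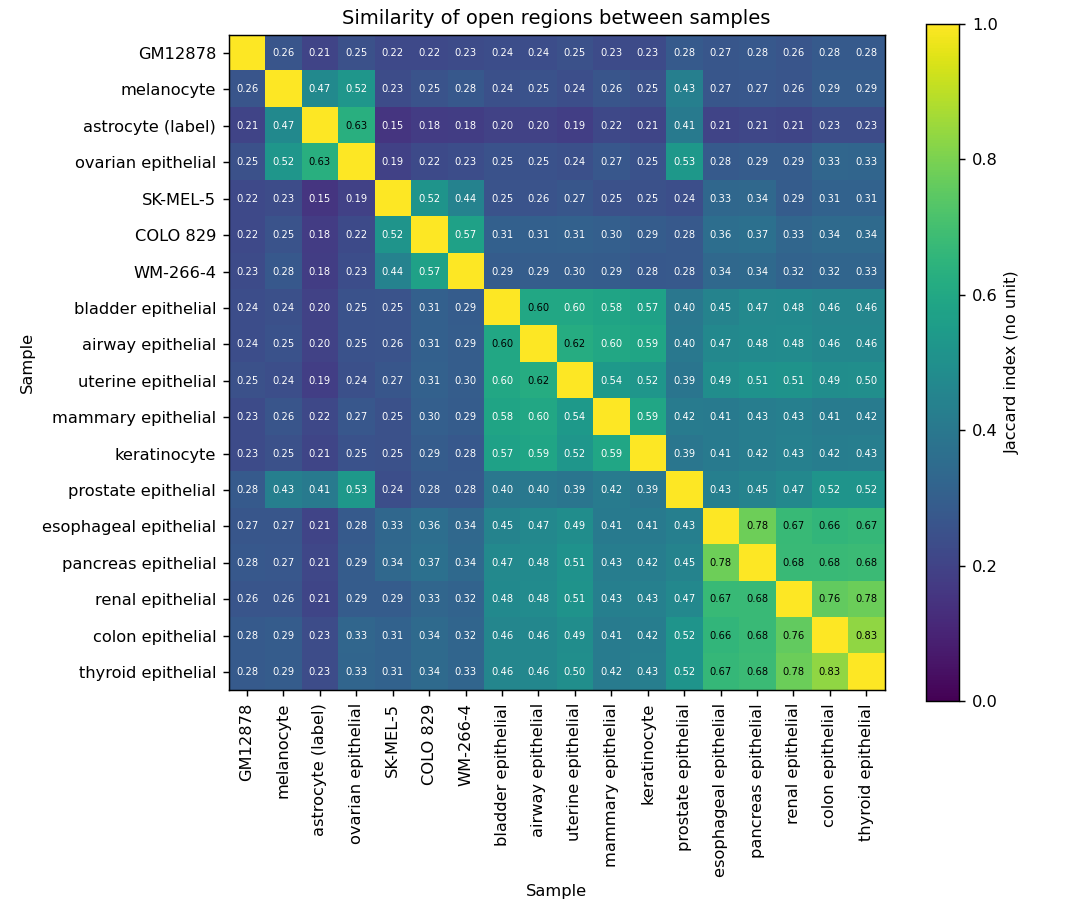
Jaccard index (no unit) between all pairs of the 18 samples, ordered by average-linkage clustering. The 5 long shared-medium lists form a block of 0.659 to 0.832, airway, bladder, mammary, uterine and keratinocyte cells another, and the melanoma lines one of 0.443 to 0.572, while short lists resemble each other.

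The library labelled astrocytes had no region of its own. The keratinocyte list contained 99.7% of its 16102 regions, the uterine list 99.3%, the airway list 99.1%, the bladder list 98.8% and the mammary list 98.2%. Of its 710 rare regions, 97.0% were open in keratinocytes (95% Wilson interval 95.5 to 98.1%), 88.0% in airway, 86.9% in uterine, 84.2% in bladder and 83.5% in mammary cells. Colon and thyroid cells had 3.38% and 5.21% of them open, and the remaining samples between 1.13% (ovarian and prostate) and 29.7% (COLO 829). The ovarian list, also short, had 99.8% of its regions open in renal cells. Of its 390 rare regions, 96.4% were open in renal and 90.5% in pancreas cells, 68.2% in uterine, 36.2% in airway, 36.2% in bladder and 10.3% in keratinocyte cells.

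In SK-MEL-5 a stretch of chromosome 9 held no peak. From 21434730 to 27726227, 6.29 Mb with 298 consensus regions, SK-MEL-5 had 0 intervals, COLO 829 had 113, WM-266-4 had 60 and the 15 other lists between 17 and 145. It included 16 consecutive regions that were open in at least 12 of the 13 other long lists, those with at least 50000 regions. The longest such closed run was 7 in COLO 829, 5 in WM-266-4, 12 in GM12878 and at most 4 in the 10 remaining long lists. Of all regions open this widely in the other long lists, SK-MEL-5 had 9.98% closed and GM12878 27.0%.

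**Figure D4:**
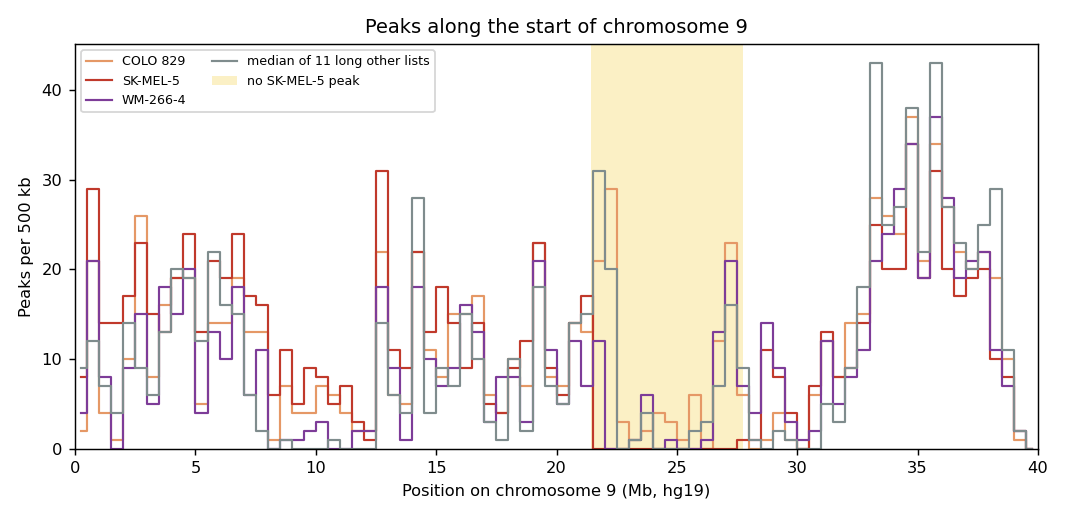
Peaks per 500 kb along the first 40 Mb of chromosome 9 (hg19) in the 3 melanoma lines and as the median of the 11 long lists of other cells. The shaded stretch of 6.29 Mb has 0 peaks in SK-MEL-5, and COLO 829 and WM-266-4 have 113 and 60 there.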

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

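In the epithelial samples grouped by culture medium, 5 of 16 extreme values lay further from the nearest other sample than Dixon's 95% critical value allows, which chance does for about 1 in 20 groups. All 5 belong to the ovarian or prostate list, and this check was added after the data were seen. Among the 6 shared-medium samples the ovarian list had the fewest regions, 21201 (next 63177), covered the least, 20.3 Mb (next 40.5 Mb), and had the widest median interval, 910 bp (next 531 bp). Among the other 5 the prostate list had the fewest regions, 34403 (next 72657), and the lowest share of its own, 0.0145% (next 4.66%). The measures within a list are related, so these are not 5 independent signals.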

How the results depend on the processing

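Of 154 recomputed values, 103 kept their direction and side of the threshold or moved little, 38 moved, 11 passed out of their threshold and 2 changed sign. A count was taken to move little when it changed by a factor of at most 1.5. This includes the melanoma-only regions, 10473 with all lines, at 15705 without SK-MEL-5 and 15258 without WM-266-4. In 500 bp bins melanoma-only units numbered 16597, those absent from melanoma 39 and pigment cell units 821, and 76.1% of the melanocyte units were open in all lines. With at least 50% of a region covered, pigment cell regions were 533, regions open in all samples 5906 and the melanocyte share 74.6%. With the wider 50% of each list, melanoma-only regions were 5480, absent 11, pigment cell 141, single-sample 47377, open in all 5411, and the melanocyte share 81.2%. Cutting lists at random to the shortest (1 draw) removed most sharing by construction: 116 melanoma-only regions, 0 absent (exact permutation p = 1), 4 pigment cell (exact permutation p = 0.238), 0 open in all, a melanocyte share of 0.805%, differences in similarity of 0.0111 for melanoma (exact permutation p = 0.143), 0.00895 for epithelial (exact permutation p = 0.285) and 0.0222 for shared-medium samples (exact permutation p = 0.0952), -6.93 points for rare melanocyte regions (exact permutation p = 0.960), and 78 and 3 windows in the melanoma and epithelial comparisons (0 and 3 higher). Keeping the widest intervals to that length gave 1190 melanoma-only, 195 absent, 138 pigment cell, 22755 single-sample and 3294 regions open in all, a melanocyte share of 40.2% and 3.45 points for rare regions (exact permutation p = 0.253). The overlap coefficient gave 0.120 for melanoma similarity (exact permutation p = 0.116) and turned the melanocyte difference to 0.0585. Without the 4 shortest lists 741 regions were absent from melanoma, 16446 open in all, and the shared-medium difference 0.255. Window counts for melanoma and epithelial cells were 1277 and 867 without the covariate (550 and 734 higher) and 7266 and 3375 without the filter (4850 and 1417 higher); 250 kb windows gave 2321 for melanoma (1279 higher and 1042 lower). Without the 6 shared-medium samples 1 epithelial window passed. Leaving out a melanoma line gave 34 to 73 absent regions, melanocyte shares of 82.4 to 86.0%, melanoma similarity differences of 0.170 to 0.282 and 2202 to 2508 windows. Leaving out the library labelled astrocytes or the airway list changed no call. Except for the random cut, the cause of these changes was not tested. The results on promoters, genes, gene lists and motifs, and their other settings, were not run. Read depth is unknown, so what a deeper library would add to the short lists was not assessed.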

Other observations

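The tests in this part were all chosen after the results were seen. The melanoma lines distributed their open regions unevenly over the chromosomes, and 11 of 22 chromosomes passed an adjusted exact permutation test. Chromosome 7 held 6.56 ± 0.150% of their regions on chromosomes 1 to 22 (SD, n = 3) and 5.24 ± 0.290% in the other samples (SD, n = 15), and chromosome 13 held 2.93 ± 0.0289% against 2.30 ± 0.190%; on both, all 3 lines lay above the other 15 samples (exact two-sided permutation p = 0.00123, adjusted over 22 chromosomes 0.00674). Chromosome 9 held 3.83 ± 0.234% against 4.33 ± 0.114% (exact permutation p = 0.00245, adjusted 0.00770) and chromosome 19 held 3.21 ± 0.117% against 4.43 ± 0.854% (exact permutation p = 0.0110, adjusted 0.0221). Against only the long lists of other cells the log2 difference on chromosome 19 was -0.308, and against all 15 samples -0.441. For chromosomes 7, 13 and 9 it was 0.309, 0.297 and -0.177 against the long lists, and 0.326, 0.351 and -0.180 against all 15. A higher share on some chromosomes lowers the shares of others, so the 11 are not independent results. WM-266-4 had no peak on chromosome 9 from 21971600 to 23342108, inside the empty stretch of SK-MEL-5, where COLO 829 had 35 and the other 15 lists a median of 14.

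The grouping of the samples was set against 99 other splits for each window comparison, 100 with the real one. For melanoma only 1 split, the real one, reached the 4026 windows called, and the highest of the others gave 159. The values argue against a random grouping for this count. However, 99 of the 815 other choices of 3 samples were drawn and the rest were not run. For epithelial cells the real split gave 1942 windows and again only 1 of 100, the real one, reached that number, a share under 0.05. The highest of the 99 others gave 1898, nearly as many. That split had 5 epithelial samples and the 3 melanoma lines in its group of 11. The lines were on the same side of it, as in the real split, so it does not show what an unrelated grouping would give. Few of the possible splits were drawn, so chance is not excluded for the 1942 windows.

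The library labelled astrocytes shares nearly all its regions with keratinocytes. A short list that keeps mostly regions open everywhere stays open as an explanation, because the comparisons go both ways. The short ovarian, prostate and melanocyte lists had 96.4, 88.4 and 67.6% of their rare regions open in their best match (renal, renal and WM-266-4) and 2, 5 and 202 regions of their own, near the 97.0% and 0 of this list for the first but not for the last, and the melanocyte, GM12878 and melanoma lists cut to its length had 20.0 to 78.1% and 118 to 2780. A mislabelled or mixed library stays open as well: the 99.7% open in keratinocytes and the 0 regions of its own are the pattern itself and no test of it. Nor is that share particular to keratinocytes, since uterine and airway cells had 99.3% and 99.1% of its regions open. Whether cultured astrocytes themselves open these regions was not tested, and marker genes were not used here.

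The close resemblance of the 5 long shared-medium lists does not come from 1 list deposited several times, since at most 1.53% of the intervals of any pair were identical. The shared medium may contribute, and its effect cannot be told apart from that of the organ. The prostate list, grown in another medium, had 66.8 ± 18.05% of its rare regions open in these 5 lists (SD, n = 5) and 67.1 ± 9.95% in the 4 long lists of other media (SD, n = 4), a difference of -0.358 points (exact two-sided permutation p = 0.960), which does not decide it.

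The empty stretch of chromosome 9 in SK-MEL-5 was set against 3 explanations. The peak threshold or list length is argued against as the whole cause, because the run of 16 closed regions was longer than the longest in each of the 13 other long lists, at most 12. Loss of the DNA and a domain of closed chromatin in this line both stay open and cannot be told apart with peak positions alone, because the 0 peaks in the run are the pattern itself. The run of 12 in GM12878 does not decide between them, since that line had 27.0% of the widely open regions closed and SK-MEL-5 had 9.98%.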
